A study of Ketogulonicigenium vulgare with 6 samples.

How the data were processed

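Total RNA of Ketogulonicigenium vulgare WSH-001, a bacterium used with a Bacillus companion in the production of 2-keto-L-gulonic acid, was measured on 6 arrays, 3 from control cells and 3 from acid-stressed cells. Per the labels' protocols, a mixed culture with B. megaterium was grown for 18 h at 30 °C and pH 7.0, and cells were then held for 2 h in fresh medium at pH 7.0 or pH 4.0. The RNA of each sample was labelled with Cy5, and a pool of the control and acid samples, labelled with Cy3, was the common reference on every array. No dyes were swapped, so a gene-specific dye effect stays in each ratio and cancels in the difference between groups.

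Spot intensity values are median pixel brightness per spot and channel, deposited as the scanner output of Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. The deposited scanner files also hold background-subtracted, dye-normalized processed intensities and a log10 ratio of red over green, per the file headers. The authors' normalized table gives 1 log2 value per group for 2301 genes, with no value per array. Its median was 0.02 for control and 0.02 for acid. The scale was taken as log2 because acid minus control gave the deposited fold within 1% for all 142 genes of the authors' lists, while the centring stays unknown. The column taken as control carries an abbreviation that no label spells out and was assigned because it is the only group column beside the pH group. The authors' deposited lists give a linear fold ratio and an unadjusted p-value from a t-test, limited to a fold of 2 and a p of 0.05, per the file headers. The title lines of those sheets state the opposite direction to their regulation column, and the regulation column was followed because the normalized values bear it out for all 142 genes. Gene symbols, products and positions were taken from the deposited table as given there, with coordinates counted from 1 and lengths divisible by 3 for all 2301 genes. The name of the genome build is not given in the sources used here.

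The array held 15208 spots for 3060 genes, with 1 probe per gene and 4 or 5 spots per probe. The design fixed before the data were examined named mean spot signals, but the files used here hold median signals, which took their place. Background was corrected with normexp and an offset of 50, and ratios were normalized by loess within each array in limma 3.58.1 under R 4.3.3, with control spots and outlier spots at weight 0. Outlier spots were left out and the spots of a probe averaged. A gene was called well above background on an array when more than 50% of its spots were so in Cy5, a share set after the data were seen. Genes well above background on all 3 arrays of at least 1 group were kept, which left 1073 genes. No spot was saturated. The median net Cy5 signal was 9 to 22 units over a background of 45 to 47, so an offset of 50 compresses fold changes, and every fold here is on that scale unless named otherwise. The number of arrays limits the precision.

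Groups were compared with limma's moderated two-sided test and Benjamini-Hochberg adjustment at 0.05, and a change of at least 2-fold was counted in addition. Of the 40 gene lists fixed before the data were examined, 33 had at least 5 genes in the test and were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Camera compares a list with the other genes, while fry tests a list against no change, so their counts answer different questions. Some fixed patterns matched genes of another function. The oxidative stress list, for example, took in 6 genes whose product contains deoxyribo. The lists were kept as fixed, and a version without such genes was added after the data were seen. Genes were named by a rule fixed before the data were examined. Among genes past the threshold whose 3 acid arrays lay on one side of all 3 controls, the rule took the 10 largest rises and falls with a known product, the 2 largest of each without one, and up to 4 members of each list past its threshold with up to 2 in the other direction. It added up to 3 members of each acid stress list that missed its threshold. Only 9 falls with a known product, 1 rise and 1 fall without one qualified.

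A gene not well above background on any array of a group is given without a fold. The fit was tested on simulated data for this comparison with 1071 genes, 200 of them changed. It recovered 79.9% of genes changed by 0.5, 91.4% of those changed by 1 and 98.9% of those changed by 2 on the log2 scale, and 4.84% of its calls were false. The simulated noise was independent between genes and arrays, with the same SD in both groups. It held no array that departs as a whole from its group, so these rates may not hold for the measured arrays.

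The scanner records place acid 1 and acid 2 in scan 1, and acid 3 with the 3 controls in scan 2. The effect was therefore also fitted with scan as a block and within scan 2, where 1 acid array is assumed to vary like the controls. Scan 1 holds acid arrays only. Further alternatives varied background correction, normalization, filters, outlier spots, array weights, the variance prior and the replicates. The methods' t-test was run on the same values.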

Results

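Gene expression was compared between K. vulgare cells held for 2 h at pH 4.0 and control cells held at pH 7.0, with 3 arrays in each group. The study design asks which genes differ between acid-stressed and control cells, and its text calls the arrays of a group biological replicates. Of the 3060 genes on the array, 875 to 1876 were well above background in Cy5 on a given array, with the highest counts on acid 1 and acid 2. The 99th percentile of the net Cy5 signal lay between 306 and 1043 units. Values are log2 ratios of the sample over the pooled reference, as mean ± SD of 3 arrays, and changes are acid minus control.

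Among the genes that passed the test, the ferredoxin gene fdx (KVU_0361), which encodes an iron-sulfur electron carrier, had the largest rise at pH 4.0. It went from -0.29 ± 0.18 in control to 1.11 ± 0.30 in acid (n = 3 each), a 2.65-fold rise (limma adjusted p = 0.016). The gene for coproporphyrinogen III oxidase (KVU_0875), an enzyme of heme synthesis, went from -0.18 ± 0.10 to 0.88 ± 0.21, a 2.09-fold rise (limma adjusted p = 0.0142). Close by on the chromosome, the heme exporter genes ccmC (KVU_0871, positions 914987 to 915724) and ccmD (KVU_0872, positions 915721 to 915876), which serve cytochrome c maturation, also rose. The gene ccmD rose 1.58-fold (limma adjusted p = 0.00852), and no fold is given for ccmC (limma adjusted p = 0.0195), which was not well above background on any control array. The cytochrome c2 gene cycA (KVU_0068) rose 1.66-fold, and the gene of a DsbB family protein (KVU_1032), which acts in disulfide bond formation, rose 1.70-fold.

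The ABC transporter ATPase gene KVU_0481 rose 2.05-fold (limma adjusted p = 0.016) and the metal transporter permease gene sitC (KVU_2163) rose 1.54-fold, although sitC turned to -0.079 with the Cy5 channel alone. KVU_1909, annotated as a peptidase of the M16 type, and KVU_2149, annotated as the precursor of SSDA2, rose by 0.66 and 0.64 on the log2 scale. The largest fall among the genes that passed the test was that of KVU_1409, an extracellular solute-binding protein gene of family 5, from 0.08 ± 0.04 to -0.83 ± 0.16 (limma adjusted p = 0.00852), although it turned to 0.023 with the Cy5 channel alone. The putative cell division gene KVU_1473 (FtsL) fell by 0.82 and the serine peptidase gene KVU_0795 fell by 0.73. On processed signals the order differed, with KVU_1473 at -2.55 and KVU_1409 at -1.23. On plasmid 1, the histidine kinase gene KVU_PA0149 (positions 134374 to 135375) fell by 0.67, as did the ABC transporter gene yliA (KVU_PA0132). The exodeoxyribonuclease gene xthA1 (KVU_2318), which acts in DNA repair, fell by 0.69 (limma adjusted p = 0.0493). Of the genes without a known function, KVU_2145 rose by 0.36 and KVU_0165 fell by 0.50. In each gene named here as passing the test, the 3 acid arrays lay on one side of the 3 controls, because the naming rule required it. The genes cycA, lepB, KVU_1473, KVU_0795, KVU_1405, yliA and xthA1 were well above background on 2 of the 3 acid arrays, appB on 2 of the 3 control arrays and KVU_1032 on 1 of them.

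**Figure D1:**
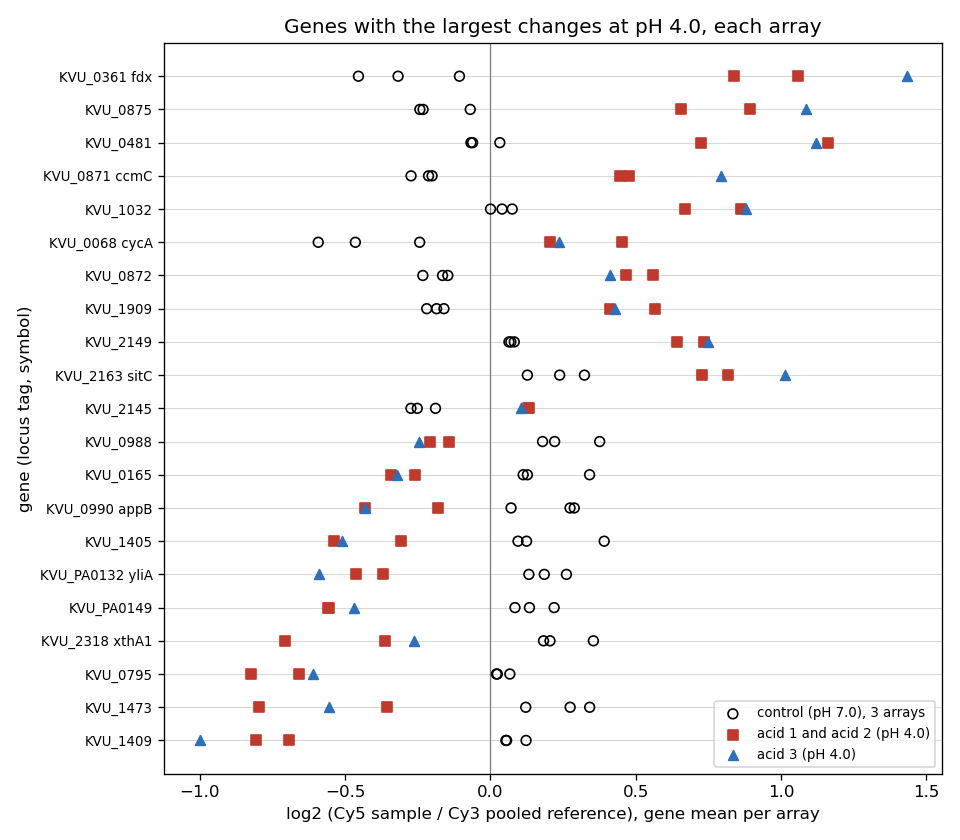
Log2 ratio of Cy5 sample over Cy3 pooled reference (horizontal axis) for the named genes with the largest changes among those that passed the test (vertical axis). Each array has 1 symbol, with open circles for the 3 controls, squares for acid 1 and acid 2 and triangles for acid 3. By the naming rule, the 3 acid arrays of each gene shown lie on one side of the 3 controls. For fdx the mean is 1.11 in acid and -0.29 in control.

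In all, 37 of 1073 genes passed the threshold, 27 higher and 10 lower at pH 4.0, and 3 of them changed at least 2-fold. These 3 were all higher, while at 2-fold 9 were higher and 3 lower with an offset of 10, 23 higher and 14 lower with processed signals, and 1 higher and 3 lower after median centring. The groups did not overlap in 348 of 1071 genes, or 32.5%, where 10% is the mean share over all splits into 3 and 3. Genes are not independent, and acid 1 and acid 2 lie in another scan than every control. The excess therefore has no error rate and cannot be assigned to acid alone. The split into higher and lower calls depended on the scaling, with 1 higher and 7 lower after median centring and 27 higher and 18 lower with processed signals. With scan as a block, 483 genes passed, 271 higher and 212 lower, and 512 passed within scan 2. Scan 1 holds no controls, so both of these counts compare acid 3 alone with the 3 controls, and acid 3 correlated across genes at only 0.180 and 0.166 with acid 1 and acid 2. Without acid 3 the count was 244, with all 37 genes kept, but acid arrays of scan 1 were then set against controls of scan 2, so scan and acid cannot be told apart in it. It was 14 without acid 1, and limma called 0 genes without control 1, control 2 or control 3, with 135, 153 and 141 genes at an unadjusted p under 0.05. At least 2-fold, 51 genes passed with scan as a block, 52 within scan 2, 7 without acid 3, 5 without acid 2 and 0 without any 1 of the controls.

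Of the fixed gene lists, 4 of 33 shifted by camera with its preset correlation, and none of these 4 passed with an estimated correlation. Other splits of the 6 arrays into 3 and 3 gave 1 to 4 lists by the same test. The peptide and amino acid transporters lay lower, with 1 of 37 measured members rising, 1 falling and 35 not passing the test, and with 1 rising and 4 falling adjusted over the list alone (camera adjusted p = 0.00143, adjusted p = 0.697 with an estimated correlation). Without acid 3 the median of these transporters was -0.07 in place of -0.14, with 7 members rising and 9 falling (camera adjusted p = 0.192). The dipeptide transporter ATPase gene KVU_1405 fell by 0.66 (limma adjusted p = 0.0358), while the dipeptide permease gene dppCch3 (KVU_0565) rose (limma adjusted p = 0.0358), with no fold given because it was not well above background on any control array. The oligopeptide transporter genes KVU_0988 and appB (KVU_0990), which the list pattern did not take in, fell by 0.46 and 0.56. The F0F1 ATP synthase list, the proton-driven enzyme of ATP synthesis, lay lower with a median of -0.23, and 0 of its 6 members passed over all genes (camera adjusted p = 0.0114, adjusted p = 0.697 with an estimated correlation). Adjusted over the list alone, 5 of them fell and 1 rose, the riser being nuoE (KVU_1827), a complex I gene by its symbol. Of those 5, atpA (KVU_0455) was not well above background on any control array. Its mean log2 Cy5 signal was 6.51 in acid against 5.97 in control, opposite to its ratio. The Cy5 signal of atpX (KVU_2444) and atpC (KVU_0458) was also higher in acid, and that of the remaining falling members was lower. Chosen after the values were seen, atpI (KVU_2441) was at -0.76 ± 0.34 in acid against 0.13 ± 0.11 in control (limma adjusted p = 0.058). Without nuoE, a change made after the values were seen, the list of 5 had a camera adjusted p of 0.000764, or 0.561 with an estimated correlation.

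The Sec and Tat secretion list lay higher, with 2 of 15 members rising, 0 falling and 13 not passing, and with 8 rising adjusted over the list alone (camera adjusted p = 0.00841, adjusted p = 0.697 with an estimated correlation). The signal peptidase I gene lepB (KVU_0159), whose product cleaves signal peptides from exported proteins, rose by 0.54 (limma adjusted p = 0.025), although it turned to -0.23 with the Cy5 channel alone. The other, KVU_2288, is annotated with a Tat signal, rose (limma adjusted p = 0.0319) and was not well above background on any control array; such a signal marks an exported protein and not the secretion machinery. Without 3 such proteins, the list of 12 had a camera adjusted p of 0.0143, or 0.561 with an estimated correlation. The ATP-dependent and periplasmic proteases lay higher in all 12 members, with a median of 0.23, and 0 passed over all genes and 1 rose adjusted over the list alone (camera adjusted p = 0.00841, adjusted p = 0.697 with an estimated correlation). None of the 33 lists passed without acid 3, where the lowest adjusted p was 0.0603. With scan as a block, which compares acid 3 alone with the controls, 4 lists passed, and none did with an estimated correlation (lowest adjusted p = 0.457). Those lying higher were complex I (adjusted p = 0.00318), the iron and heme list (adjusted p = 0.0316) and the chaperones (adjusted p = 0.0444), each with an adjusted p of 0.457 with an estimated correlation. Of the lists above, the transporters (median -0.36, adjusted p = 5.52e-06) passed, and the proteases (0.41, adjusted p = 0.056), ATP synthase (-0.25, adjusted p = 0.0814) and secretion (0.26, adjusted p = 0.177) did not. Within scan 2, again acid 3 alone and with none passing with an estimated correlation (lowest adjusted p = 0.659), the transporters (adjusted p = 1.35e-06), complex I (adjusted p = 0.00213), the iron and heme list (adjusted p = 0.0334), the chaperones (adjusted p = 0.0334) and the proteases (adjusted p = 0.0392) passed, and ATP synthase (adjusted p = 0.0585) and secretion (adjusted p = 0.118) did not.

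Several other lists linked to acid stress did not pass with all 6 arrays and no block. In the iron, iron-sulfur cluster and heme list, 4 of 24 members rose, among them ccmC, ccmD and sitC, and 20 did not pass (camera adjusted p = 0.0517). The authors' deposited lists hold 4 of its 60 annotated members as higher and 7 as lower. The falls there include iron uptake genes not kept for the test here, such as fecC (KVU_PA0164) at 3.83-fold. Of the 12 members of the chaperone list, 0 passed, and without acid 3 there was 1 rise and 1 fall (camera adjusted p = 0.604). Its member grpE (KVU_2246) was at 0.00 ± 0.03 in acid against -0.29 ± 0.10 in control (limma adjusted p = 0.0725). Of the 22 members of the oxidative stress list, xthA1 alone passed, and it is a DNA repair gene that the pattern took in by its name. The glutathione synthetase gene gshB (KVU_2593) was at 0.19 ± 0.11 against -0.06 ± 0.06 (limma adjusted p = 0.139). In the list of sorbose, sorbosone and PQQ genes 0 of 10 passed over all genes, and 2 rose adjusted over the list alone. It did not pass by camera (adjusted p = 0.255) but did by fry (adjusted p = 0.0453). Its member KVU_1910, given the symbol pqqE but the product of a peptidase of the M16 type, was at 0.43 ± 0.17 against -0.19 ± 0.16 (limma adjusted p = 0.058). The list pattern did not take in KVU_2149, the precursor of SSDA2, which rose by 0.64 (limma adjusted p = 0.00852). KVU_2166, annotated as the precursor of SSDA1, is 5.74-fold lower in the authors' deposited lists. In the values used here it was at -0.995 for acid minus control, the same direction, and did not pass (limma adjusted p = 0.355). The ornithine decarboxylase gene (KVU_1206) was at -0.52 ± 0.19 against -0.30 ± 0.08 (limma adjusted p = 0.342), a difference of -0.22 that was -0.11 without acid 3, and 0 of the 6 members of its list passed. The potassium uptake gene KVU_1653 was the 1 measured member of its list, which was too small to test, at -0.03 ± 0.07 against 0.10 ± 0.01 (limma adjusted p = 0.263).

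The authors' deposited table lists 70 genes higher and 72 lower at pH 4.0. In the authors' deposited table the largest listed rise is 7.25-fold for KVU_0153, annotated as an uncharacterized protein with a predicted role in c-type cytochrome biogenesis. In the values used here KVU_0153 was at 1.76 for acid minus control and missed the threshold (limma adjusted p = 0.0606). Among the falls in the authors' deposited table are 20.5-fold for KVU_0912, a substrate-binding protein gene of an ABC transporter, and 8.18-fold for pqqB (KVU_2034), a gene of PQQ synthesis, PQQ being the cofactor of several sugar dehydrogenases. In the values used here pqqB was at -0.24 for acid minus control and did not pass (limma adjusted p = 0.809), with acid 1 and acid 2 at -1.11 and -0.15 and acid 3 at 0.89, against 0.12 ± 0.14 in control. Of the 43 listed higher genes tested here, 9 passed here as higher, where independent lists would share 1.08, and of the 40 listed lower genes 8 passed as lower, where independent lists would share 0.373. Without acid 3 these counts were 40 and 25, and on processed signals without acid 3 they were 43 and 39. With all 6 arrays, 42 of the 43 and 36 of the 40 had the direction of the deposited list. Both calls draw on the same set of arrays, so the overlap is not independent evidence, and the lists differ both in processing and in the weight of acid 3. Without acid 3, both set acid arrays of scan 1 against controls of scan 2, so any effect of scan is shared by both. In a regression across 2300 genes, the authors' deposited acid value had a weight of 0.539 ± 0.00334 (SE) on acid 1, 0.466 ± 0.00336 on acid 2 and 0.00116 ± 0.0013 on acid 3, while the weights of the 3 controls in the deposited control value lay between 0.324 and 0.358.

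**Figure D2:**
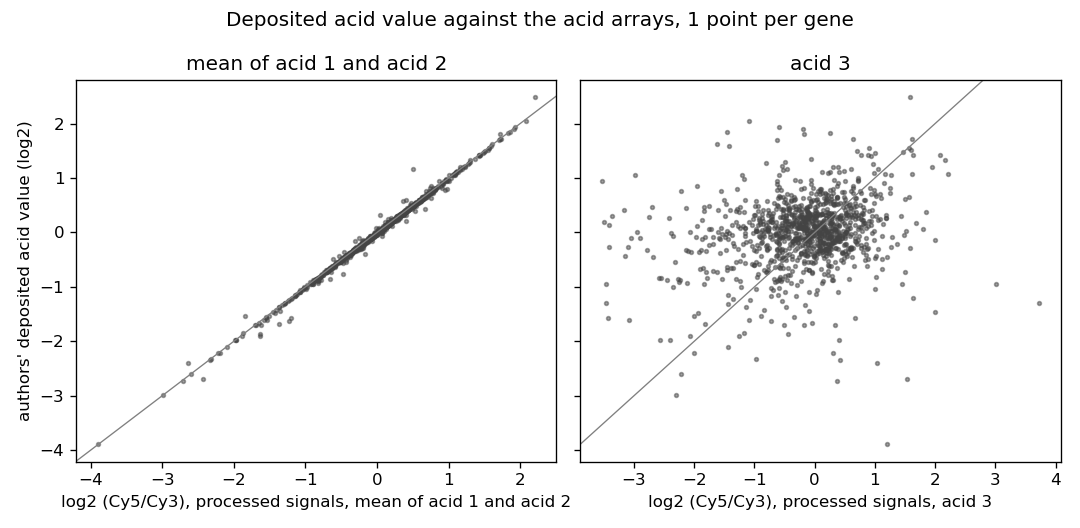
Authors' deposited acid value (vertical axis, log2) against the log2 ratio of processed signals (horizontal axis) for the mean of acid 1 and acid 2 on the left and for acid 3 on the right, 1 point per gene tested, with the line of equality. The points follow the line on the left and scatter widely on the right, where the correlation over the 2300 genes of the table was 0.107.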

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

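The alternatives within scan 2, without acid 3 on processed signals, and without list members of another function were chosen after seeing the data. All 37 genes kept their direction under every alternative that tested them except the Cy5 channel alone, where 34 did. These genes were selected on the same arrays, so a kept direction is not independent evidence. Against 37 genes, the count was 57 without background correction, 8 after median centring, 15 for genes well above background on all 6 arrays, 66 with outlier spots kept, 483 with scan as a block, 214 with array weights, 512 within scan 2 and 264 on processed signals without acid 3. It was 0 after scaling between arrays and 0 with the Cy5 channel alone, where limma gave 204 and 138 genes at an unadjusted p under 0.05. Leaving out 1 replicate gave 0 to 244 genes. Against 3 genes changed at least 2-fold, there were 37 on processed signals, 12 with an offset of 10, 0 after scaling, 0 with Cy5 alone, 6 with outlier spots kept, 51 with scan as a block, 8 with array weights, 52 within scan 2 and 86 on processed signals without acid 3, and 0 to 7 when 1 replicate was left out. The methods' t-test at the authors' limits gave 5 genes on the main values and 61 on processed signals, and 10 and 20 genes of any size after Benjamini-Hochberg adjustment. With the replicate block, 0 genes passed at either limit (197 at an unadjusted p under 0.05) and 5 lists did. Deviations of same-numbered arrays correlated at 0.285, 0.0587 and 0.177, against -0.225 to 0.0972 for arrays of different numbers. Deviations were taken from the group mean of each gene, so higher values for some pairs of arrays force lower ones for others. These values leave a pairing by number open, and the main fit did not pair the arrays. Against 4 lists, 8 passed without a filter, and 0 with Cy5 alone, 0 for genes well above background on all 6 arrays, 0 on processed signals without acid 3 and 0 with an estimated correlation. Leaving out 1 replicate gave 0 to 6 lists. By fry, which tests against no change, 10 lists passed (not the peptide and amino acid transporters, fry adjusted p = 0.404). The overlap with the deposited lists fell from 17 to 3 genes when 2-fold was required. Cy5 alone turned sitC (-0.079), KVU_1409 (0.023) and lepB (-0.23), and processed signals without acid 3 turned the transporter list (a median of 0.00402). Median centring moved the median of all genes from 0.03 to -0.08. The cause of these changes was not tested. Not run were median against mean signals and the brightest probe, since the files gave no mean signals and 1 probe per gene, and the deposited normalized values, which have 1 value per group. Low signal over background limits what could be called, with 858 genes never well above background.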

Other observations

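The comparison of the acid arrays between scans, the regression on the deposited values and the tests of a shared scan shift, of an exchange with a control and of an outside sample were chosen after the results were seen; the spot noise and neighbour tests were written before their values, although the neighbour pattern had been noticed among the genes that passed.

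Between acid 1 and acid 2 of scan 1 and acid 3 of scan 2, 440 of 1073 genes differed, 232 higher and 208 lower in scan 1 (limma with scan as a block). Acid 3 is a single array in this comparison and was assumed to vary like the other groups, so these counts and lists describe that array and not a response of acid cells in general. Peptide and amino acid transporters lay higher in acid 1 and acid 2, with 20 of 37 members higher and 2 lower (camera adjusted p = 0.000131, adjusted p = 0.478 with an estimated correlation). Complex I genes, which encode the proton-pumping NADH dehydrogenase, lay lower, with 11 of 20 members lower and 1 higher (camera adjusted p = 0.00568, adjusted p = 0.478 with an estimated correlation). Among single genes, chosen after their values were seen, pykA (KVU_2558, pyruvate kinase) was at -0.01 in acid 1 and acid 2 against -1.58 in acid 3, cysT (KVU_1113, a sulfate transporter permease) at -0.13 against -1.58, and nuoC (KVU_1830, complex I) at 0.19 against 1.25. Chaperone genes lay lower in acid 1 and acid 2, with 5 of 12 lower and 1 higher (camera adjusted p = 0.029, adjusted p = 0.478 with an estimated correlation).

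Acid 3 stood apart from the other acid arrays, with correlations across genes of 0.180 and 0.166 against 0.839 between acid 1 and acid 2; genes are not independent replicates. A shift shared by all arrays of scan 2 would raise the correlation of acid 3 with the controls. It averaged -0.0334, below the 0.319 to 0.421 of acid 1 and acid 2. The reference pool holds control and acid RNA, so an acid response moves the groups to opposite sides of it. A strong response in acid 3 could thus hide such a shift, and a shift shared by acid 1 and acid 2 was not tested. The correlation therefore cannot decide on an effect of scan. Spot noise is argued against by alternate spots of acid 3, which correlated at 0.87, and an exchange with a control by the lowest correlation between controls, 0.715. The changes of acid 3 and of the other acid arrays from control correlated at 0.242 with the same sign in 58.5% of genes, against 0.298 and 60.0% simulated for unchanged groups on the same 3 controls, while their covariance of 0.0309 exceeded the simulated 0.00282 by 0.0281. The simulated groups held no change at all, so their correlation and sign share are no baseline for arrays with changes of their own. The covariance exceeded what the shared controls give, but a sample under another stress could also give this. A wrong label, a culture that responded differently and an effect of scan therefore cannot be told apart.

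The deposited acid value gave acid 3 a weight of 0.00116, which argues against a mean of the 3 acid arrays, and no source used here says how that value was made.

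Neighbouring genes changed together. Over 374 pairs of neighbours on the same strand, fold changes correlated at 0.617 (permutation p = 1e-04, the smallest that 10000 permutations can give, one-sided, adjusted p = 2e-04 over 2 tests). Over 143 pairs on opposite strands the correlation was 0.0893 (permutation p = 0.1, adjusted p = 0.1), a difference of 0.528 with a 95% bootstrap interval of 0.329 to 0.751. The bootstrap drew pairs as independent units although consecutive pairs share a gene, so this interval may be too narrow. The lower value argues against an effect of position or probe order whatever the strand as the whole cause, and the same-strand value is consistent with joint transcription, as a hypothesis. In acid 3 alone the same-strand correlation was 0.658 and the opposite-strand one 0.333, so an effect of position stays open for that array.

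Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For genes, 1 split, the real one, reached 37, and the highest other gave 0. At 2-fold, 1 split reached 3 and the highest other gave 0. For lists, 2 splits reached 4, and the highest other also gave 4, from control 1, control 3 and acid 1 against the rest. Every other split gave at least 1 list, so the number of lists passing camera at the preset correlation does not set the real split apart.

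On the replicons, 2 of 41 tested genes of plasmid 1 fell and 0 rose, against 8 falls and 27 rises among 992 tested genes of the chromosome. The share of falls on plasmid 1 against the other replicons had a two-sided Fisher's exact p of 0.0528, or 0.158 adjusted over the 3 replicons. On plasmid 2, limma called 0 of 40 tested genes, with 3 at an unadjusted p under 0.05.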
